A study of Rattus norvegicus with 18 samples.

How the data were processed

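Mucosal scrapings of the rat jejunum were profiled on 18 Affymetrix rat whole-genome arrays, 3 per group, for vehicle and for palbociclib, abemaciclib and ribociclib at the doses given in the labels. The deposited values are log2 expression values, 1 per probe set and array, between 2.86 and 14.34. RMA, Affymetrix Expression Console and Transcriptome Analysis Console are named in the submitters' processing notes, without versions or settings. RMA as usually run corrects background, equalises the distribution of signal between arrays and summarises the probes of a probe set, so a change in the total amount of RNA per cell would not be visible. The arrays carry no count of reads, and their number limits the precision. Detection calls were not used here, so a fold with 1 group near or below the array medians (5.41 to 5.51), such as those of Gzma, Gzmb, Mcpt9 and Slc28a1 with abemaciclib at 120 mg/kg/day, rests on a signal not shown to be above background. No 2 arrays held identical values, and the correlation of pairs of arrays lay between 0.918 and 0.993.

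Arrays were assigned to groups by the treatment label. Replicates are lettered A to C. The labels do not say which animal each array came from or how long it was dosed, so p-values measure the spread between these arrays. Of the 31099 probe sets, 57 were controls and were left out, 20826 had 1 gene symbol, 436 had several and were not named, and 9780 were unnamed in the platform annotation used here. Entrez identifiers of 20758 probe sets matched the RefSeq gene table, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over all arrays, which left 14217 genes, 4525 of them with more than 1 probe set. No genome was used, and genes are given by symbol.

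The tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where the text says otherwise. A model with 1 mean per group was fitted over all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, eBayes with an intensity trend), and 11 comparisons and an F test over the groups were taken from it. p-values were two-sided and adjusted by the method of Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1 for a single gene. Intervals are 95% intervals from the same limma model. Fold differences are 2 to the power of the log2 difference. The other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

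In all, 45 lists of pathway genes, epithelial cell types, other cell types of the gut wall and intestinal regions with at least 5 measured genes were tested with limma's camera, which compares the genes of a list with all other genes. Camera was run with a preset correlation between genes of 0.01 and again with the correlation estimated from the data. With an estimated correlation no list passed in any of the 11 comparisons. Counts of members higher or lower are given for adjustment over all genes and for genes "adjusted over the list alone". Some genes belong to more than 1 list.

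The genes named are the 8 with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap, leaving out placeholder symbols, or the 3 with the smallest p where no gene passed. To these were added up to 4 members of each described list with the smallest p and a set fixed in advance, Cdk4, Cdk6, Ccnd1, Rb1, Mki67, Lgr5, Axin2, Muc2, Alpi, Fabp1, Cyp1a1 and Cdkn1a. Olfm4, Lyz1 and Sis, which belonged to that set, were not analysed here.

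The alternatives were quantile re-normalization, centring each array on its median, leaving out genes below the 30th percentile of mean signal, the mean of all probe sets of a gene, every probe set as its own feature, eBayes without the trend, a fold of at least 1.5, only the groups compared in the fit, the replicate letter as a block, the estimated correlation and leaving out each array in turn. An RNA quality covariate, the log2 difference between the 3′ and 5′ beta-actin control probe sets, was added after seeing the data.

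The limma step was tested on simulated data in which 200 of the 14217 genes were changed, 50 at each of 4 fold sizes. The simulated noise was normal, independent between genes and without arrays that stand apart, so recovery on the real arrays can be lower. For palbociclib 100 mg/kg/day against vehicle, Slc34a2 had a real log2 difference of 3.33 and did not pass in limma (adjusted p = 0.559). For palbociclib 100 mg/kg/day against vehicle it recovered 24% of 1.5-fold, 62% of 2-fold, 96% of 4-fold and 98% of 8-fold changes, with 9 false among 149 calls. For palbociclib 30 mg/kg/day it recovered 30%, 58%, 100% and 100%, with 5 false among 149 calls. For abemaciclib 120 mg/kg/day it recovered 36%, 58%, 96% and 100%, with 9 false among 154 calls.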

Results

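RNA from mucosal scrapings of the jejunum, the middle stretch of the small intestine, was hybridised to 18 Affymetrix rat arrays in 6 groups of 3. Male Sprague Dawley rats had received vehicle, palbociclib at 30 or 100 mg/kg/day, abemaciclib at 36 or 120 mg/kg/day, or ribociclib at 300 mg/kg/day, by oral gavage once daily. All 3 compounds inhibit CDK4 and CDK6, the kinases that act with D-type cyclins to phosphorylate the retinoblastoma protein and let cells pass from G1 into S phase. Palbociclib, a pyridopyrimidinone, and ribociclib, a pyrrolopyrimidine, share a cyclopentyl group and a piperazinyl-pyridinylamino side chain. Abemaciclib instead joins a pyrimidine to a benzimidazole and carries an N-ethylpiperazine. The design text of the study gives dosing for 4 and 15 days, and the labels do not say which applied to an array. A difference in duration within or between groups therefore cannot be excluded. Vehicle arrays came from rats given methyl cellulose, the vehicle of palbociclib, whereas abemaciclib and ribociclib were given in another vehicle. Vehicle and compound therefore cannot be told apart where those compounds are compared with vehicle or palbociclib. The comparisons of the abemaciclib doses, and of abemaciclib with ribociclib, do not carry that difference in vehicle. The title of abemaciclib 120 mg/kg/day replicate B gives a dose of 100 where its treatment label gives 120. Expression was measured as log2 signal for 14217 genes, with array medians between 5.41 and 5.51. A gene is said to rise or fall where its adjusted p was under 0.05 in limma with n = 3 arrays per group, and each gene named for the size of its change had arrays of the compared groups that did not overlap.

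The 6 groups differed for 3212 of the 14217 genes (22.6%) in limma's F test across groups. Against vehicle, 2560 genes changed with abemaciclib at 120 mg/kg/day, 531 with ribociclib at 300 mg/kg/day and 296 with abemaciclib at 36 mg/kg/day. No gene passed for palbociclib at 100 or 30 mg/kg/day, where 1023 and 357 genes had an unadjusted p under 0.05 in limma. If no gene changed, a share of 0.05 of the 14217 genes would be expected below that p, which lies between these counts. Without abemaciclib 120 replicate A the F test called 1580 genes, and with an RNA quality covariate added after seeing the data it called 1246.

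**Figure D1:**
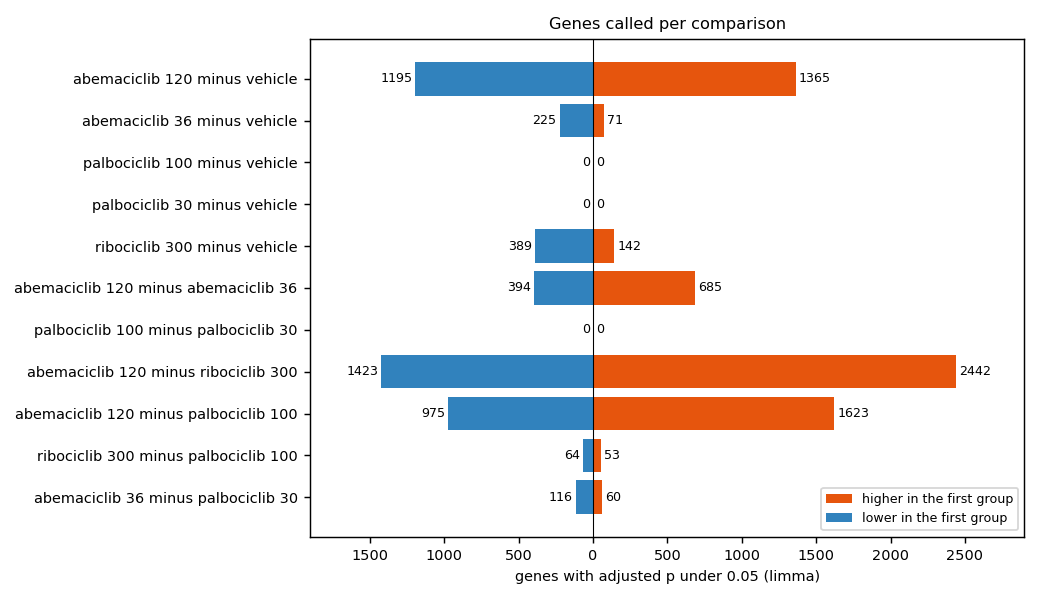
Number of genes called higher (above 0) or lower (below 0) in each of the 11 comparisons, limma adjusted p under 0.05, 3 arrays per group. Abemaciclib at 120 mg/kg/day against vehicle gave 1365 higher and 1195 lower genes, and each palbociclib dose gave 0.

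With abemaciclib at 120 mg/kg/day, the genes that rose most against vehicle were Fabp6, the ileal bile acid-binding protein (log2 difference 6.05, SE 1.55, 66.1-fold, adjusted p = 0.0123), and Ly6al (5.63, SE 1.14, 49.6-fold, adjusted p = 0.00281). They were followed by Dmbt1, a glycoprotein of mucosal surfaces (21.1-fold), Spink4, a secreted protease inhibitor of goblet cells (18.7-fold), Smoc2, a marker of crypt-base stem cells (16.4-fold), and Gpr15lg, a ligand of the lymphocyte receptor GPR15 (14.7-fold). Ccna2, which encodes cyclin A, rose 13.2-fold (3.72, SE 0.71, adjusted p = 0.00188) and Cdca3, a regulator of mitotic entry, 12.3-fold (adjusted p = 0.000497). The genes that fell most were granzyme A (Gzma, -5.54, SE 0.69, 46.4-fold lower, adjusted p = 9.03e-05), granzyme B (Gzmb, 36.6-fold lower), the mast cell protease Mcpt9 (27.3-fold lower) and the retinol dehydrogenase Rdh7 (-4.69, 25.8-fold lower). The surface protein Cd7 was 21.1-fold lower, the chemokine Ccl5 18.6-fold lower, the cytokine Il36b 18.3-fold lower and the nucleoside transporter Slc28a1 15.5-fold lower (-3.96, SE 0.39, adjusted p = 2.13e-05). Mean signal of Gzma was 5.46 ± 1.05 (SD, n = 3) against 10.99 ± 0.36 in vehicle, and that of Fabp6 was 13.29 ± 0.31 against 7.24 ± 1.78.

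Cell division genes rose together with abemaciclib at 120 mg/kg/day. Of 39 measured genes of the G2/M and mitosis list, 37 rose and 0 fell (39 rose when adjusted over the list alone), with a median log2 difference of 2.45 (5.47-fold) and an adjusted p = 3.97e-29 in the camera set test. Among them were the spindle checkpoint kinases Ttk (8.44-fold) and Bub1b (3.57-fold), the kinetochore motor Cenpe (2.97-fold) and the transcription factor Foxm1 (2.44-fold). Of 36 genes for G1/S and DNA replication, 27 rose and 0 fell (31 over the list alone, median 1.28, adjusted p = 7.44e-19). These included Cdk2 (4.49-fold), E2f8 (4.43-fold), Uhrf1 (2.92-fold) and thymidine kinase Tk1 (5.49-fold). Ribosome biogenesis and MYC targets rose in 21 of 23 genes (22 over the list alone, median 1.86, adjusted p = 3.23e-17), with Dkc1, a subunit of the snoRNP that modifies ribosomal RNA, at 5.78-fold and Polr1b, a subunit of RNA polymerase I, at 3.23-fold. Intestinal stem cell genes rose in 11 of 15 (11 over the list alone, median 0.92, adjusted p = 3.51e-07). These included Aqp4 (7.08-fold), Prom1 (6.18-fold), Cdca7 (4.62-fold) and Lgr5 (0.70, SE 0.15, 1.63-fold). With an estimated correlation between genes, the adjusted p = 0.207 for each of these 4 lists. The 3 abemaciclib arrays had median G2/M differences from the vehicle mean of 2.70, 2.24 and 2.42. The difference between the 3′ and the 5′ beta-actin control probe sets, which grows as RNA degrades, was 1.05, 0.92 and 0.86 on these arrays and 0.65, 0.79 and 0.57 on the vehicle arrays.

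At the same dose T and NK cell genes fell in 16 of 21 and rose in 0 (17 fell over the list alone, median -2.06, 4.18-fold lower, adjusted p = 7.66e-15, and adjusted p = 0.207 with an estimated correlation). Among these were Nkg7 (5.43-fold lower), the T cell kinase Lck (6.97-fold lower) and Cd8a (4.54-fold lower). MHC class II genes fell in 8 of 9 (9 over the list alone, median -3.18, 9.07-fold lower, adjusted p = 1.44e-07, and adjusted p = 0.207 with an estimated correlation). These included the invariant chain Cd74 (8.57-fold lower), RT1-DMb (9.88-fold lower) and RT1-Da (10.1-fold lower). Interferon-stimulated genes fell in 16 of 34 (17 over the list alone, median -0.95, adjusted p = 4.64e-06, and adjusted p = 0.507 with an estimated correlation). These included Igtp (9.56-fold lower), Irf7 (9.60-fold lower) and Parp14 (3.10-fold lower). Macrophage and dendritic cell genes fell in 7 of 19 (10 over the list alone, median -0.94, adjusted p = 0.000108, and adjusted p = 0.414 with an estimated correlation), with Itgax at 6.19-fold lower and the signalling adaptors Fcer1g at 3.73-fold lower and Tyrobp at 4.00-fold lower. B and plasma cell genes had a median of -0.29, with 2 of 10 lower (adjusted p = 0.118). For mast cell genes, despite the fall of Mcpt9, the median was -0.09, with 2 of 15 lower (adjusted p = 0.18).

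Genes of mature enterocytes fell in part with abemaciclib at 120 mg/kg/day. The lipid absorption list fell with 7 of 21 genes lower and 0 higher (9 lower over the list alone, median -0.45, adjusted p = 4.56e-05, and adjusted p = 0.327 with an estimated correlation). These included the fatty acid translocase Cd36 (5.78-fold lower), the sterol transporter Abcg8 (4.31-fold lower) and Apoc3 (2.25-fold lower). Brush border genes fell in 5 of 23 (8 over the list alone, median -0.42, adjusted p = 0.000108, and adjusted p = 0.486 with an estimated correlation), with the trehalose-splitting enzyme Treh at 7.78-fold lower, Ggt1 at 5.45-fold lower and the angiotensin-converting enzyme Ace at 4.17-fold lower. Nutrient transporters had 9 lower and 1 higher of 22 (10 and 1 over the list alone, median -0.62, adjusted p = 0.000361, and adjusted p = 0.377 with an estimated correlation), and the glucose transporter Slc2a2 was 3.04-fold lower. Xenobiotic metabolism genes fell in 7 of 20 (7 over the list alone, median -0.46, adjusted p = 0.00149, and adjusted p = 0.207 with an estimated correlation). These included Cyp2j4 (2.51-fold lower), Cyp3a18 (2.39-fold lower) and the nuclear receptor Nr1i3 (3.01-fold lower).

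With abemaciclib at 120 mg/kg/day, cholesterol synthesis rose in 9 of 20 genes and fell in 0 (11 and 1 over the list alone, median 0.81, adjusted p = 0.00033, and adjusted p = 0.586 with an estimated correlation), with the sterol oxidase Msmo1 at 3.56-fold. The heat shock list rose with 6 of 15 higher and 1 lower (8 and 2 over the list alone, median 0.82, adjusted p = 0.00659, and adjusted p = 0.377 with an estimated correlation), with the mitochondrial chaperonin Hspd1 at 3.74-fold. Integrated stress response genes had 9 of 30 higher and 1 lower (9 and 3 over the list alone, median 0.34, adjusted p = 0.0226, and adjusted p = 0.586 with an estimated correlation), led by genes of serine and asparagine synthesis, Psat1 (11-fold), Phgdh (3.53-fold) and Asns (3.12-fold). Wnt targets rose in 8 of 17 and fell in 0 (8 over the list alone, adjusted p = 0.0228, and adjusted p = 0.486 with an estimated correlation), where the median of 0.06 lay near 0 and the mean was 0.57. Wnt targets that rose included Myc (6.25-fold), Axin2 (1.72, SE 0.35, 3.29-fold) and Znrf3 (1.90-fold). Unfolded protein response genes had 1 of 20 higher, 0 over the list alone, with a median of 0.48 (adjusted p = 0.0226, and adjusted p = 0.669 with an estimated correlation).

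Of the genes fixed in advance, Ccnd1, which encodes cyclin D1, rose by 2.34 on the log2 scale (SE 0.53, 5.06-fold, adjusted p = 0.00572) and Cdk4 by 1.81 (SE 0.46, 3.51-fold, adjusted p = 0.0115). Rb1 was lower (-0.55, SE 0.18, adjusted p = 0.0477). The proliferation marker Mki67 (1.74, SE 0.64, adjusted p = 0.0712), Cdk6 (-0.06, adjusted p = 0.806), Cdkn1a (0.32, adjusted p = 0.414), the goblet cell mucin Muc2 (0.10, adjusted p = 0.618), Fabp1 (-0.16, adjusted p = 0.141), the alkaline phosphatase Alpi (-1.77, adjusted p = 0.0636) and Cyp1a1 (-1.91, adjusted p = 0.401) did not pass. The list of CDK4, CDK6 and their partners and inhibitors had 5 of 18 higher and 4 lower with a median of 0.23 (adjusted p = 0.416), with Ccne1, which encodes cyclin E1, at 3.85-fold and Ccnd2 at 3.77-fold, and with the CDK4 and CDK6 inhibitor Cdkn2d 3.25-fold lower.

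For abemaciclib at 120 mg/kg/day, 1365 genes were higher and 1195 lower than vehicle in limma (18% of those tested), and the arrays of 2509 did not overlap. Called genes were picked on these same arrays, so the lack of overlap is no separate support. Without abemaciclib 120 replicate A the count was 1349, without vehicle replicate C 1473 and with the RNA quality covariate 1596. In all, 1213 genes were called in every fit that left out 1 array. Calls were lost without abemaciclib 120 replicate A for Fabp6 (adjusted p = 0.0504) and Cdk4 (0.0619), without vehicle replicate C for Fabp6 (0.0722), and without each of the 6 arrays in turn for Rb1 (highest 0.234). List calls were lost without abemaciclib 120 replicate C for the unfolded protein (0.227) and integrated stress (0.0856) responses, without vehicle replicate C for the former (0.0991) and without abemaciclib 120 replicate B, with dim genes left out or with only these groups fitted for Wnt targets (0.123, 0.161 and 0.126).

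**Figure D2:**
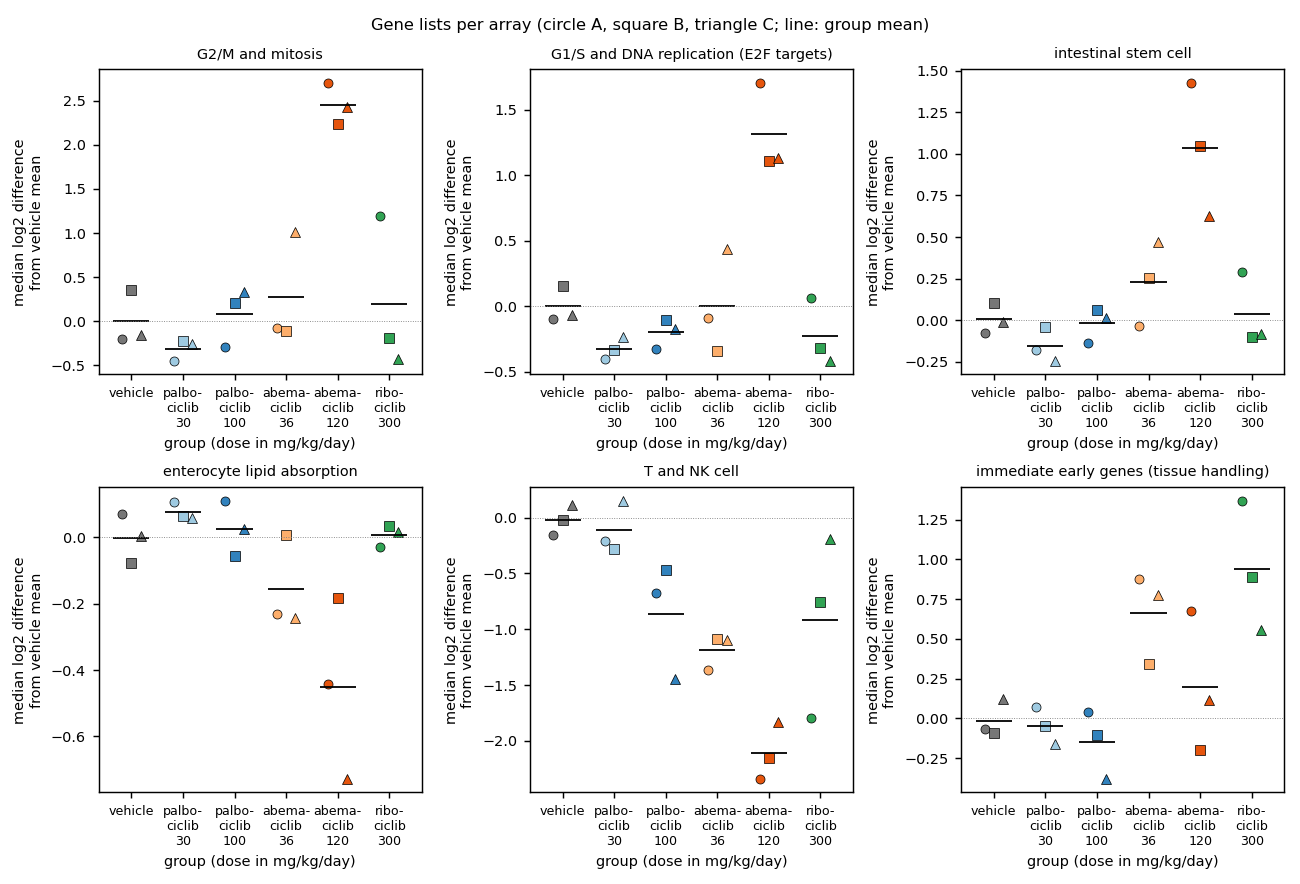
Median log2 difference of the members of 6 gene lists from the vehicle mean, for each of the 18 arrays (circle, replicate A, square, B, triangle, C), with a line at the mean of each group. The G2/M medians of the abemaciclib 120 mg/kg/day arrays were 2.70, 2.24 and 2.42, and the T and NK cell medians were -2.34, -2.15 and -1.83.

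With abemaciclib at 36 mg/kg/day, the largest fall among the genes named was in Frat2, a binding partner of the kinase GSK3 (-3.28, SE 0.33, 9.71-fold lower, adjusted p = 0.000208), with a mean of 6.44 ± 0.21 (SD, n = 3) against 9.72 ± 0.02 in vehicle. Hexim1, an inhibitor of the transcription elongation factor P-TEFb, was 5.80-fold lower, the death ligand Tnfsf10 6.04-fold lower and the ubiquitin ligase Trim36 5.63-fold lower. Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell 9.36-fold (adjusted p = 0.00923), and the glucocorticoid-responsive genes Klf15 (6.33-fold lower) and Sgk1 (6.21-fold lower) also fell. Among genes that rose were the mitochondrial carrier Slc25a25 (3.09, SE 0.49, 8.52-fold, adjusted p = 0.00491), Haus6, a subunit of the spindle-binding augmin complex (6.20-fold, adjusted p = 0.0029), the replication factor Mcm10 (12.5-fold, adjusted p = 0.0221), Mtfr2 (11.7-fold), Phlda1 (9.44-fold) and the immediate early transcription factor Egr1 (7.86-fold). The digestive protease Ctrc rose 4.59-fold and the Wnt target Axin2 3.09-fold (1.62, SE 0.35, adjusted p = 0.024).

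Of 21 T and NK cell genes, 6 fell with abemaciclib at 36 mg/kg/day and 0 rose (14 fell over the list alone, median -1.18, 2.26-fold lower, adjusted p = 4.91e-10, and adjusted p = 0.689 with an estimated correlation). These included Nkg7 (2.96-fold lower), Cd8a (2.80-fold lower) and Lck (2.63-fold lower). Immediate early genes, which respond within minutes to growth factors and tissue handling, had 1 of 16 higher (4 over the list alone, median 0.72, adjusted p = 0.000361, and adjusted p = 0.689 with an estimated correlation). Ribosome biogenesis genes had a median of 0.55 with 0 of 23 passing (adjusted p = 6.4e-05, and adjusted p = 0.848 with an estimated correlation). Stem cell genes had a median of 0.25 (1 of 15 passing, adjusted p = 0.0172), interferon-stimulated genes -0.34 (0 of 34, adjusted p = 0.0172) and G2/M genes 0.25 (0 of 39, adjusted p = 0.0328), each with adjusted p = 0.848 with an estimated correlation. G1/S genes had 1 of 36 higher and a median of 0.01 (adjusted p = 0.904). In the CDK4 and CDK6 list, 0 of 18 rose and the inhibitors Cdkn2d (3.83-fold lower) and Cdkn1b (2.63-fold lower) fell, with a median of 0.02, a mean of -0.15 and an adjusted p = 0.546. Mki67 (-0.49, adjusted p = 0.827), Ccnd1 (0.69, adjusted p = 0.652), Cdk4 (0.32, adjusted p = 0.843), Cdkn1a (0.58, adjusted p = 0.247) and Lgr5 (0.25, adjusted p = 0.5) did not pass.

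For abemaciclib at 36 mg/kg/day, 71 genes were higher and 225 lower in limma (2.08%), and the arrays of all 296 did not overlap, which is no separate support for genes picked on these arrays. The count was 96, 67 and 60 without vehicle replicates A, B and C and 46, 531 and 166 without abemaciclib 36 replicates A, B and C. A total of 38 genes, among them Frat2, Haus6, Slc25a25, Hexim1, Tnfsf10, Trim36, Ctrc, Cdkn2d and Nkg7, were called in every such fit. Axin2 and Egr1 kept their calls only without abemaciclib 36 replicate B (highest adjusted p = 0.113 and 0.0983 without another array). The other genes named lost theirs without at least 1 array (highest 0.155, for Lck without abemaciclib 36 replicate A). List calls were lost without abemaciclib 36 replicate C for ribosome biogenesis (adjusted p = 0.0942), stem cell (0.17), interferon (0.541) and G2/M genes (0.947, median -0.07), without vehicle replicate A for stem cell (0.0531) and G2/M genes (0.169) and without vehicle replicate C for G2/M genes (0.226), where the replicate letter as a block also ended the call (0.0596). The number of lists called was 6, and 13, 11, 16 and 2 without vehicle replicate B and abemaciclib 36 replicates A, B and C, and 10 with only these groups fitted.

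Between the abemaciclib doses, 685 genes were higher and 394 lower at 120 than at 36 mg/kg/day in limma (7.59%). Psat1, an enzyme of serine synthesis, was 9.27-fold higher at the higher dose (3.21, SE 0.45, adjusted p = 0.000795), Shcbp1 8.43-fold and Ttk 7.41-fold. Granzyme A was 14.6-fold lower at the higher dose (-3.87, SE 0.69, adjusted p = 0.00291), the protease inhibitor Slpi 14.7-fold lower, Rdh7 10.5-fold lower and Slc28a1 8.55-fold lower. G2/M genes were higher in 38 of 39 (median 2.14, adjusted p = 1.21e-33) and G1/S genes in 27 of 36 (median 1.37), each with adjusted p = 0.215 with an estimated correlation. Mki67 was 4.67-fold higher at the higher dose (2.22, SE 0.64, adjusted p = 0.0424). The T and NK cell list was lower in 9 of 21 genes (median -0.81, adjusted p = 8.55e-09). Macrophage and dendritic cell genes were lower in 10 of 19 (median -1.55, adjusted p = 9.11e-10) and MHC class II genes in 8 of 9 (median -2.78). Csf1r, the receptor of the macrophage growth factor, fell by 2.26 on the log2 scale. Over all lists of this comparison the smallest adjusted p with an estimated correlation was also 0.215, with 9 of 45 lists called higher and 17 lower at the preset one. Among these were the ileum list, higher (median 0.74, adjusted p = 0.0489), and the proximal small intestine list, lower (-0.73, 0.0489). Axin2 did not differ detectably (0.09, 95% interval -0.64 to 0.83, adjusted p = 0.913). The count of 1079 genes fell to 397 without abemaciclib 120 replicate A, 483 without abemaciclib 36 replicate A, 579 without abemaciclib 36 replicate B, 435 with the RNA quality covariate and 309 with only these groups fitted, and 358 genes were called in every fit that left out 1 array. The call of Mki67 held in only 1 of the 6 such fits, with an adjusted p of up to 0.186.

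With ribociclib at 300 mg/kg/day, the genes that rose included the vasodilator peptide Adm (3.58, SE 0.45, 12-fold, adjusted p = 0.000722), the urokinase receptor Plaur (3.39, SE 0.47, 10.5-fold), the stress-responsive transcription factor Maff (7.59-fold, adjusted p = 0.000547), Ppp1r15a, which directs dephosphorylation of the translation factor eIF2 alpha (6.78-fold), and Ly6al (47.2-fold, adjusted p = 0.0156). The genes that fell included Angptl4, an inhibitor of lipoprotein lipase (-2.96, SE 0.48, 7.77-fold lower, adjusted p = 0.00494), the death ligand Tnfsf10 (7.02-fold lower), interleukin 1 beta (Il1b, 5.65-fold lower), Ppargc1a, the coactivator of mitochondrial biogenesis (-2.47, SE 0.28, 5.54-fold lower, adjusted p = 0.000547), and the natural killer cell receptor gene Cd244l1 (5.21-fold lower). Bco1, which cleaves beta-carotene, was 5.24-fold lower (adjusted p = 0.0379) and Ugt2b15 10.0-fold lower (adjusted p = 0.0451). Timp1, an inhibitor of matrix metalloproteinases, rose 3.87-fold, Insig1, a regulator of sterol synthesis, 3.33-fold and the stress cytokine Gdf15 2.17-fold. Fabp6 was 46.2-fold above vehicle without passing (5.53, adjusted p = 0.0584).

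With ribociclib the lists for oxidative phosphorylation, fatty acid oxidation and T and NK cells shifted down. In the oxidative phosphorylation list 2 of 20 genes fell and 0 rose (15 fell over the list alone, median -0.53, 1.45-fold lower, adjusted p = 1.68e-07, and adjusted p = 0.816 with an estimated correlation), the former being the complex I subunits Ndufs3 (1.79-fold lower) and Ndufv2 (1.71-fold lower). Fatty acid oxidation and PPAR alpha targets fell in 3 of 24 (8 over the list alone, median -0.41, adjusted p = 1.8e-05, and adjusted p = 0.465 with an estimated correlation). In the T and NK cell list 5 of 21 genes fell (10 over the list alone, median -1.09, 2.13-fold lower, adjusted p = 2.93e-06, and adjusted p = 0.816 with an estimated correlation). Among these were Cd8a (3.20-fold lower) and Nkg7 (2.63-fold lower), and the medians on the 3 arrays were -1.79, -0.76 and -0.19. Immediate early genes rose in 4 of 16 (11 over the list alone, median 1.02, 2.02-fold, adjusted p = 1.68e-07, and adjusted p = 0.259 with an estimated correlation), namely Egr1 (5.35-fold), Dusp1 (2.92-fold), Egr2 (2.87-fold) and Klf6 (2.46-fold). Integrated stress response genes had 3 of 30 higher and 1 lower (median 0.37, adjusted p = 0.00533), cholesterol synthesis genes 2 of 20 higher (median 0.30, adjusted p = 0.045), enteroendocrine genes 1 of 21 higher (median 0.23, adjusted p = 0.0179) and NF-kB targets 1 of 23 higher (Tnfaip3, 4.73-fold) and 1 lower (median 0.21, adjusted p = 0.0429). Interferon-stimulated genes had a median of 0.63 with 0 of 34 passing (adjusted p = 0.0217). With an estimated correlation the adjusted p = 0.852 for the cholesterol and interferon lists and 0.816 for the other 3. Cdkn2d was 2.82-fold lower, while Mki67 (-1.19, adjusted p = 0.302), Cdkn1a (0.81, adjusted p = 0.0648), Axin2 (-0.23, adjusted p = 0.73) and Cdk4 (-0.51, adjusted p = 0.547) did not pass.

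Markers of deeper gut layers were measured alongside ribociclib. Smooth muscle genes had a median of 0.62 (0 of 16 passing, adjusted p = 0.00316, and adjusted p = 0.816 with an estimated correlation), fibroblast genes 0.37 (1 of 23 higher, adjusted p = 0.0179, and adjusted p = 0.852 with an estimated correlation) and endothelial genes 0.24 (0 of 16 passing, adjusted p = 0.0179, and adjusted p = 0.822 with an estimated correlation). The smooth muscle median of ribociclib replicate A was 1.59. Without that array none of these lists passed, with adjusted p = 0.402 for smooth muscle, 0.838 for fibroblast genes (median -0.18) and 0.578 for endothelial genes, which also did not pass with dim genes left out (0.105). Without vehicle replicate A the endothelial (adjusted p = 0.0629) and fibroblast (0.0757) lists did not pass either.

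For ribociclib, 142 genes were higher and 389 lower in limma (3.73%), and the arrays of 528 of the 531 did not overlap, again no separate support for genes picked on these arrays. The count was 207, 124 and 120 without vehicle replicates A, B and C, 1317 and 273 without ribociclib replicates A and C and 29 with only these groups fitted. A total of 86 genes, among them Adm, Plaur, Maff, Ppp1r15a, Angptl4, Tnfsf10, Il1b, Ppargc1a, Cd8a and Nkg7, were called in every fit that left out 1 array. Ly6al lost its call without vehicle replicates A (adjusted p = 0.0518), B (0.0545) or C (0.0652). Bco1, Ugt2b15, Tnfaip3 and the immediate early and complex I genes named lost theirs without at least 4 of the 6 arrays (highest 0.183, for Ugt2b15 without vehicle replicate C). List calls were lost without ribociclib replicate B for the integrated stress response (0.15) and interferon (0.618) lists, and without ribociclib replicate C for enteroendocrine genes (0.274). Without ribociclib replicate A, NF-kB targets (0.461) and cholesterol synthesis (0.838, median 0.04, with the direction of the test turned) did not pass. Calls were also lost without vehicle replicate A for the interferon (0.0536) and NF-kB lists (0.0551), without vehicle replicate B for the NF-kB, enteroendocrine and cholesterol lists (0.0581 each) and without vehicle replicate C for the cholesterol list (0.0839). With the RNA quality covariate the NF-kB, cholesterol and interferon lists did not pass (adjusted p = 0.0629, 0.0506 and 0.0506). Nor did the NF-kB list with dim genes left out (0.0795) or quantile re-normalization (0.0541), and the cholesterol list with only these groups fitted (0.0517).

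With palbociclib at 100 mg/kg/day no gene passed in limma, where 1023 genes had an unadjusted p under 0.05. The smallest adjusted p, 0.109, belonged to Nkg7, a granule protein of cytotoxic lymphocytes (-1.37, SE 0.23), Cd244l1 (-1.64, SE 0.28) and Ccdc80 (-1.20, SE 0.20). T and NK cell genes had a median of -0.94 (1.92-fold lower), with 0 of 21 passing over all genes and 9 lower over the list alone (adjusted p = 4.22e-12, and adjusted p = 0.746 with an estimated correlation). Other members of that list were Cd8a (-1.11, adjusted p = 0.508), Cd3d (-1.43, adjusted p = 0.508) and Lck (-1.13, adjusted p = 0.543). Macrophage and dendritic cell genes had a median of -0.56 (adjusted p = 0.0023) and G1/S genes -0.21 (adjusted p = 0.00759), each with 0 genes passing and adjusted p = 0.92 with an estimated correlation. Mki67 was -0.31 (adjusted p = 0.927) and Cdkn2d -0.89 (adjusted p = 0.559). The macrophage list lost its call without palbociclib 100 replicate C (adjusted p = 0.155) and the G1/S list without palbociclib 100 replicate A (0.0697) or vehicle replicate B (0.0971). In limma, Ccdc80 was called without palbociclib 100 replicate A (-1.41, adjusted p = 0.0374) and Adora2b, chosen after its values were seen, without vehicle replicate A (-1.44, adjusted p = 0.0332). With only these groups fitted 6 lists rather than 3 were called, and 5 were called with dim genes left out or without palbociclib 100 replicate C.

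With palbociclib at 30 mg/kg/day no gene passed in limma, where 357 genes, fewer than expected by chance, had an unadjusted p under 0.05. The smallest adjusted p was 0.998, for Fgd4 (-0.47, SE 0.12), Abcc8 (0.26, SE 0.07) and Armcx2 (-0.24, SE 0.07). G1/S and DNA replication genes had a median of -0.34 (adjusted p = 4.87e-07, and adjusted p = 0.973 with an estimated correlation), with the helicase subunits Mcm2 at -0.86 and Mcm6 at -1.12. NRF2 targets, genes of the oxidative stress response, had a median of -0.27 (adjusted p = 0.00161, and adjusted p = 0.672 with an estimated correlation), with Ephx1 at -2.29, Gclc at -1.07 and Nqo1 at -1.0. Ribosome biogenesis genes had a median of -0.28 (adjusted p = 0.000704), with the rRNA methyltransferase Fbl at -1.35, and fibroblast genes a median of -0.60 (adjusted p = 0.00441), each with adjusted p = 0.973 with an estimated correlation. The heat shock list (median -0.35, adjusted p = 0.0354) and the G2/M list (median -0.29, adjusted p = 0.04) also passed, and over all lists the smallest adjusted p with an estimated correlation was 0.672. Without vehicle replicate B the calls were lost for ribosome biogenesis (adjusted p = 0.155), fibroblast (0.093), heat shock (0.0734) and G2/M genes (0.893). Without palbociclib 30 replicate C they were lost for fibroblast (0.155), heat shock (0.226) and G2/M genes (0.259), and without palbociclib 30 replicate A for G2/M genes (0.141, and 0.126 with dim genes left out). The number of lists called was 6, and it was 2 without vehicle replicate B, 12 without vehicle replicate A and 10 without palbociclib 30 replicate B.

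Between the palbociclib doses no gene passed in limma, where 619 genes, fewer than expected by chance, had an unadjusted p under 0.05. The smallest adjusted p was 0.557, for Cd8a (-1.45, 95% interval -2.01 to -0.89, lower at 100 mg/kg/day), Cd200r1 (-0.86) and Cd37 (-0.65). T and NK cell genes had a median of -0.75 at 100 relative to 30 mg/kg/day, with 6 lower over the list alone (adjusted p = 5.97e-14, and adjusted p = 0.256 with an estimated correlation). NRF2 targets had a median of 0.32 (adjusted p = 1.36e-05, and adjusted p = 0.148 with an estimated correlation). In all, 9 of 45 lists were called higher and 3 lower, among them G2/M genes (median 0.37, adjusted p = 0.000559), MHC class II genes (-0.64, adjusted p = 0.000559) and interferon-stimulated genes (-0.36, adjusted p = 4.98e-05), with adjusted p = 0.833, 0.791 and 0.833 with an estimated correlation. These 3 calls were lost without palbociclib 100 replicate B (0.0505), palbociclib 100 replicate C (0.0978) and palbociclib 30 replicate B (0.246), in that order. The smooth muscle (median 0.24, adjusted p = 0.0301) and fibroblast lists (0.21, 0.0473) were also called higher in camera, with adjusted p = 0.833 and 0.842 with an estimated correlation. Axin2 was 0.94 higher without passing (adjusted p = 0.997). Fitted on these groups alone, Fam111a passed (-6.83, adjusted p = 0.0235), and with every probe set as its own feature a probe set of RT1-CE5 did (-1.98, adjusted p = 0.0287), both chosen after their values were seen.

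The compounds were then compared with each other at the doses used, which differed, as did the vehicle between palbociclib and the other compounds. Abemaciclib at 120 mg/kg/day had 2442 genes higher and 1423 lower than ribociclib at 300 mg/kg/day in limma (27.2%). The proliferation genes Pclaf (15.6-fold), Top2a (10.7-fold) and Ccna2 (11.8-fold), the transcription factor Myb (15.1-fold), the transferrin receptor Tfrc (12.7-fold) and Smoc2 (3.69, SE 0.58, 12.9-fold) were higher with abemaciclib. Rdh7 (-4.43, SE 0.58, 21.5-fold lower), the cytidine deaminase Cda (18-fold lower), the antiviral genes Rsad2 (17.7-fold lower), Irf7 (16.6-fold lower) and Isg15 (16.0-fold lower), and granzyme A (15.6-fold lower) were lower with abemaciclib. G2/M genes were higher in 38 of 39 (median 2.31, adjusted p = 1.57e-20) and G1/S genes in 32 of 36 (median 1.51), each with adjusted p = 0.311 with an estimated correlation. Interferon-stimulated genes were lower in 19 of 34 (26 over the list alone, median -1.74, adjusted p = 9.55e-09, and adjusted p = 0.311 with an estimated correlation). Oxidative phosphorylation genes were higher in 12 of 20 (16 over the list alone, median 0.58, adjusted p = 5.5e-06, and adjusted p = 0.402 with an estimated correlation). These included Ndufa4 (1.21) and Ndufs3 (0.98). Of 45 lists, 7 were called higher and 15 lower. Mki67 (2.93, SE 0.64, 7.62-fold), Cdk4 (5.0-fold), Ccnd1 (4.81-fold) and Axin2 (3.87-fold) were higher with abemaciclib. No difference was detected for Cdk6 (-0.01), Muc2 (0.14, 95% interval -0.10 to 0.38) or Alpi (-0.43, 95% interval -1.76 to 0.91). The count of 3865 genes was 2118 without abemaciclib 120 replicate A, 2426 without ribociclib replicate C, 1408 with the RNA quality covariate and 1378 with only these groups fitted, and 1770 genes were called in every fit that left out 1 array.

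Abemaciclib at 120 mg/kg/day had 1623 genes higher and 975 lower than palbociclib at 100 mg/kg/day in limma (18.3%). Fabp6 was higher by a log2 difference of 8.59 (SE 1.55, adjusted p = 0.00154), against palbociclib levels of 4.16, 4.43 and 5.52 that lay near or below the array medians and were not shown to be above background. The palbociclib array at 4.43, replicate B, was also high in the proximal intestine genes Pdx1 (6.73) and Onecut2 (10.17), and without it the Fabp6 difference was 8.45 (adjusted p = 0.00717). Smoc2 was 14.3-fold higher, Psat1 12.6-fold, the mitotic kinase Cdk1 11.9-fold (3.57, SE 0.66) and the helicase subunit Mcm4 11.8-fold (adjusted p = 8.23e-05). Rdh7 was 24.0-fold lower, the alcohol dehydrogenase Adh4 17.6-fold lower (-4.14, SE 0.61) and granzyme A 16.5-fold lower. G2/M genes were higher in 38 of 39 (median 2.28, adjusted p = 1.43e-26) and stem cell genes in 11 of 15 (median 1.12), while nutrient transporters were lower in 13 of 22 (median -1.0, adjusted p = 3.26e-06), T and NK cell genes in 13 of 21 (median -1.07, adjusted p = 6.58e-07) and MHC class II genes in 8 of 9 (median -2.63). Over all lists of this comparison the smallest adjusted p with an estimated correlation was 0.221, with 8 of 45 lists called higher and 10 lower at the preset one. The ileum list, which holds Fabp6, was among those called higher (median 0.78, adjusted p = 0.0357), while the proximal small intestine list did not pass (-0.86, 0.0696). Axin2 was 2.60-fold higher (adjusted p = 0.012) and Mki67 was higher by 2.05 (adjusted p = 0.0348), the latter without a call in any of the 6 fits that left out 1 array (highest adjusted p = 0.136). Axin2 lost its call without palbociclib 100 replicate C (adjusted p = 0.0557) or abemaciclib 120 replicate A (0.071). The count of 2598 genes was 1344 without abemaciclib 120 replicate A, 1455 without palbociclib 100 replicate A and 970 with the RNA quality covariate, and 1137 genes were called in every fit that left out 1 array.

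Ribociclib at 300 and palbociclib at 100 mg/kg/day, which also differed in vehicle, differed for 117 genes, 53 higher and 64 lower with ribociclib in limma (0.823%). Maff was 7.64-fold higher (2.93, SE 0.34, adjusted p = 0.000873) and Adm 7.79-fold. Fabp6 was higher by 8.07 on the log2 scale (SE 1.55, adjusted p = 0.0269), against the same palbociclib levels near or below the array medians. Ppargc1a was 6.47-fold lower (-2.69, SE 0.28, adjusted p = 0.00074), Il1b fell by 2.06 on the log2 scale and the CBP-binding regulator Cited2 was 3.75-fold lower. Oxidative phosphorylation genes had 2 of 20 lower (16 over the list alone, median -0.67, adjusted p = 8.19e-14, and adjusted p = 0.415 with an estimated correlation), and immediate early genes 2 of 16 higher (10 over the list alone, median 1.15, adjusted p = 9.18e-12, and adjusted p = 0.0546 with an estimated correlation), among 9 of 45 lists called higher and 3 lower. The ileum list, which holds Fabp6 (median 0.79, adjusted p = 0.00028), and the fibroblast list (0.71, 0.00028) were among those called higher in camera. So were the endothelial (0.29, 0.00181) and smooth muscle lists (0.56, 0.0354). With an estimated correlation their adjusted p was 0.391, 0.779, 0.635 and 0.779, in that order. No difference was called for Mki67 (-0.88, 95% interval -2.23 to 0.47), Axin2 (-0.58, 95% interval -1.31 to 0.16), Cdk4 (-0.27, 95% interval -1.24 to 0.70) or Lck (-0.34, 95% interval -1.01 to 0.34). The count was 69, 17 and 18 without palbociclib 100 replicates A, B and C, 641, 309 and 40 without ribociclib replicates A, B and C, 0 with only these groups fitted in limma, 219 without dim genes and 195 with the replicate letter as a block. Fabp6 kept its call in 2 of the 6 fits that left out 1 array (highest adjusted p = 0.127, without palbociclib 100 replicate B), while Maff, Adm, Ppargc1a, Il1b and Cited2 were among the 13 genes called in all 6.

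At the lower doses, abemaciclib at 36 mg/kg/day had 60 genes higher and 116 lower than palbociclib at 30 mg/kg/day in limma (1.24%). Slc25a25 was 11-fold higher (3.46, SE 0.49, adjusted p = 0.00341), Haus6 7.98-fold, the ephrin receptor Epha2 6.13-fold, Axin2 4.68-fold (2.23, SE 0.35, adjusted p = 0.00623) and Egr1 11.3-fold (adjusted p = 0.0111). Pdk4 (11.6-fold lower), Frat2 (-3.53, SE 0.33, 11.6-fold lower, adjusted p = 0.000129), Ppargc1a (4.88-fold lower) and Cd8a (3.54-fold lower) were lower with abemaciclib. Ribosome biogenesis genes had 1 of 23 higher (16 over the list alone, median 0.94, adjusted p = 7.16e-10, and adjusted p = 0.559 with an estimated correlation). T and NK cell genes had 2 of 21 lower (12 over the list alone, median -1.0, adjusted p = 6.97e-09, and adjusted p = 0.512 with an estimated correlation). In all, 13 of 45 lists were called higher and 6 lower, among them G2/M (median 0.53, adjusted p = 7.83e-05, and adjusted p = 0.695 with an estimated correlation) and G1/S genes (median 0.31, adjusted p = 0.00073, and adjusted p = 0.629 with an estimated correlation), both higher and neither called without abemaciclib 36 replicate C (adjusted p = 0.131 and 0.185). Lists of other cell types were also higher in camera, with fibroblast genes at a median of 1.03 (adjusted p = 7.83e-05) and macrophage and dendritic cell genes at 0.42 (0.00226). Smooth muscle genes had a median of 0.29 (0.0212) and endothelial genes 0.185 (0.00935). Each of these had adjusted p = 0.629 with an estimated correlation. No difference was called for Mki67 (-0.21, 95% interval -1.56 to 1.14) or Cdk4 (0.82, 95% interval -0.15 to 1.79). The count of 176 was 73, 43 and 35 without palbociclib 30 replicates A, B and C, 32, 775 and 61 without abemaciclib 36 replicates A, B and C and 15 with only these groups fitted. Egr1 kept its call in 3 of the 6 fits that left out 1 array (highest adjusted p = 0.0702), and the other genes named here were among the 22 called in all 6.

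**Figure D3:**
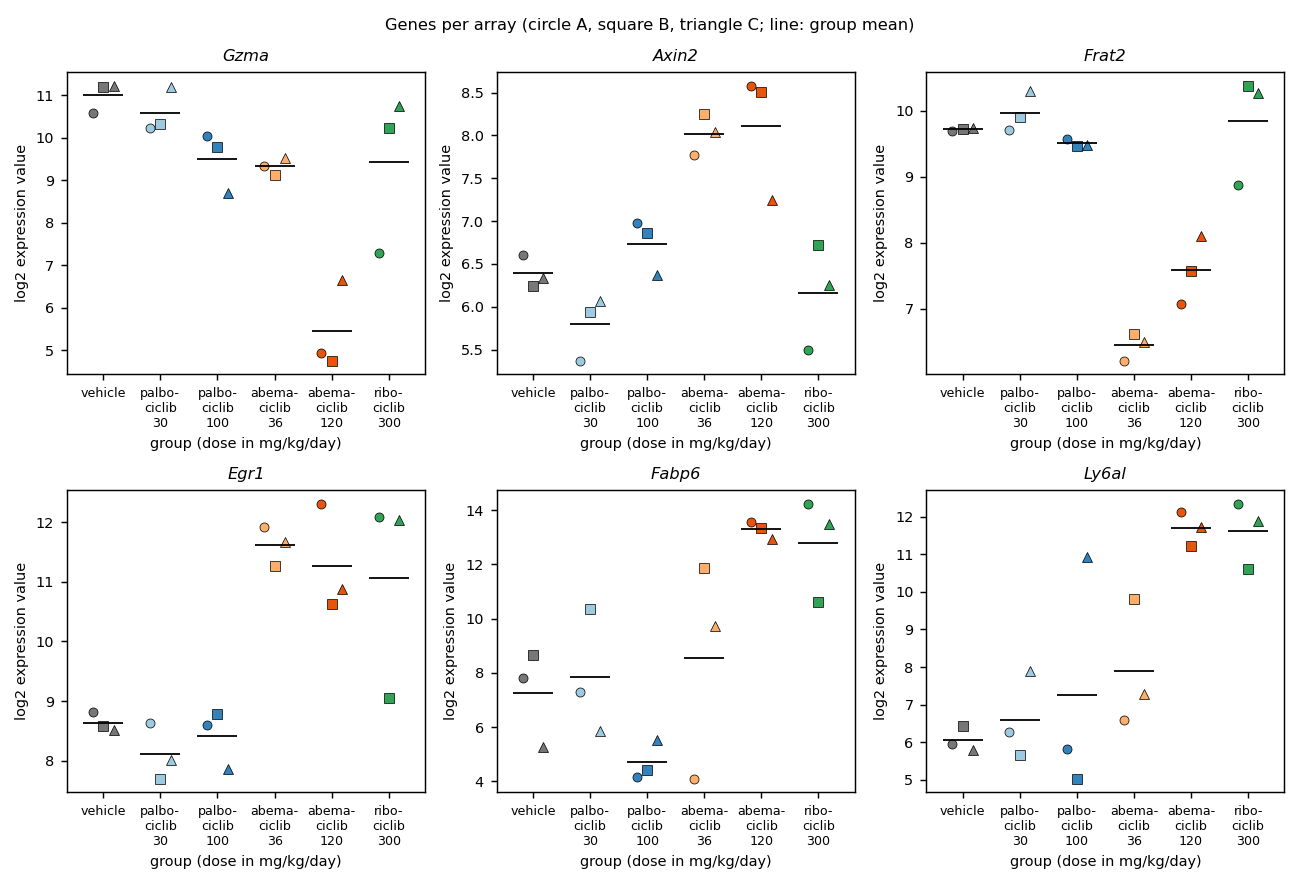
Log2 signal of 6 genes on each of the 18 arrays (circle, replicate A, square, B, triangle, C), with a line at the mean of each group. Frat2 lay between 6.21 and 6.62 on the abemaciclib 36 mg/kg/day arrays and between 9.70 and 9.74 on the vehicle arrays, while Fabp6 ranged from 4.10 to 11.85 within the former group.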

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

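The tests of RNA integrity, deeper scraping, a larger share of crypt epithelium, 1 high vehicle array, lymphoid follicle tissue and sampling nearer the ileum were chosen after the data were seen, and the spread used to judge RNA integrity and the need to pass with an estimated correlation for crypt epithelium were set after their values were seen.

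The rise of cell division genes with abemaciclib at 120 mg/kg/day went with a larger 3′ to 5′ difference of beta-actin on the same arrays. With that difference as a covariate the median G2/M shift was 2.40 (quartiles of the members 1.81 and 2.94) against 2.45 without it, and 36 of the 37 called genes were still called, which argues against lower RNA integrity as the whole cause. The other vehicle, a question also raised after the data were seen, was shared by both abemaciclib doses. At 36 mg/kg/day the median G2/M shift against the vehicle arrays was 0.25, with 0 of 39 genes passing. At 120 relative to 36 mg/kg/day 38 of 39 were higher (median 2.14, camera adjusted p = 1.21e-33, and 0.215 with an estimated correlation). That argues against the difference in vehicle as the whole cause. Deeper scraping stays open, since the smooth muscle, fibroblast and endothelial lists shifted by -0.16 on average (SE 0.36) and by -0.62 to 0.52 on the single arrays. A larger share of crypt epithelium stays open, since 4 of 4 lists it needs passed at the preset correlation, stem cell genes higher and lipid absorption, brush border and transporter genes lower, but none with an estimated one (adjusted p = 0.207, 0.327, 0.486 and 0.377). A direct effect of the compound on dividing cells is not separated from such a change in cell make-up by these arrays and was not tested.

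The T and NK cell list shifted down against vehicle at the preset correlation with abemaciclib at 120 (16 of 21 genes passing) and 36 mg/kg/day (6 of 21), ribociclib (5 of 21) and palbociclib at 100 mg/kg/day (0 of 21 in limma, median -0.94), and in none with an estimated one (adjusted p = 0.207, 0.689, 0.816 and 0.746). For abemaciclib at 120 mg/kg/day, the median shift lay between -2.11 and -1.98 when each vehicle array was left out in turn, which argues against 1 vehicle array with many T cells. With the RNA quality covariate it was -2.33 against -2.06 without it, and all 16 called genes were still called, which argues against lower RNA integrity as the whole cause. Less lymphoid follicle tissue in the scrapings stays open: the B and plasma cell list shifted by -0.29 with members between -1.80 and 0.12, but only 3 of its 10 members had a vehicle mean above a log2 signal of 6. A lower number of intraepithelial lymphocytes, or lower expression in them, was not tested.

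Fabp6, a gene of the ileum, was 66.1-fold higher than vehicle with abemaciclib at 120 mg/kg/day and ranged from 5.25 to 8.67 on the vehicle arrays and from 4.10 to 11.85 on the abemaciclib 36 mg/kg/day arrays. Sampling nearer the ileum could raise it, and without Fabp6 the ileum list had a median of 0.28 with 4 of 8 members higher and 4 lower by value. Of these, Slc10a2 (2.45, adjusted p = 0.0182), Nr1h4 (1.64, adjusted p = 0.0241) and Muc3 (1.08, adjusted p = 0.0327) passed, in 2, 2 and 1 of the 6 fits that left out 1 array (highest 0.0934, 0.103 and 0.118), and none of the lower ones did. The proximal small intestine list had a median of -0.38 over 8 members, of which Slc46a1 passed (-2.16, adjusted p = 0.0117, and called in 5 of the 6 fits, highest 0.0599). Against vehicle neither list passed as a whole (adjusted p = 0.26 with Fabp6 included, and 0.262). At 120 relative to 36 mg/kg/day camera called the ileum list higher (median 0.74, adjusted p = 0.0489) and the proximal list lower (-0.73, 0.0489). Against the higher palbociclib dose the ileum list was higher (0.78, 0.0357) and the proximal list did not pass (-0.86, 0.0696). Neither passed against ribociclib (0.812 and 0.552). With an estimated correlation none of these calls held (0.471, 0.309 and 0.424). Position along the gut and an effect of the compound thus cannot be told apart for Fabp6, and position was not tested for other genes.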

How the results depend on the processing

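The RNA quality covariate was added after seeing the data, and all other settings were planned. Quantile re-normalization, median centring, the mean of all probe sets, eBayes without the trend and a fold of at least 1.5 kept every gene count within 1.5 times, and no named gene turned its direction under any setting while passing in the full fit or under that setting. With dim genes left out, 5 lists were called for palbociclib 100 against vehicle and 219 genes for ribociclib against palbociclib 100. With every probe set as its own feature, 1 was called between the palbociclib doses. With only the compared groups fitted, the gene counts were 29 for ribociclib, 309 between the abemaciclib doses, 1 between the palbociclib doses, 1378 for abemaciclib 120 against ribociclib, 0 for ribociclib against palbociclib 100 (limma, 117 in the full fit) and 15 for abemaciclib 36 against palbociclib 30. Fewer arrays estimate the spread in such fits, and it is no longer shared with the other groups, but neither was tested as the cause. In these fits 10, 6 and 11 lists were called for abemaciclib 36, palbociclib 100 and palbociclib 30. With the RNA quality covariate, 1246 genes differed among groups, and the counts were 1596 for abemaciclib 120, 435 between the abemaciclib doses, 1408 for abemaciclib 120 against ribociclib and 970 against palbociclib 100. With the estimated correlation, 0 lists were called in each of the 7 planned list comparisons. With the replicate letter as a block, 195 genes were called for ribociclib against palbociclib 100 and no other gene or list count moved by over 1.5 times. No clear pairing of the arrays by letter was seen, but the check had no set threshold and cannot exclude it. Of 45 same-letter pairs 19 correlated above 0.1 (from -0.311 to 0.593, mean 0.061, against a mean of -0.031 for different letters). Among the 18 arrays, 7 correlated best with their own letter. Leaving out 1 array at a time gave 1580 to 4138 genes in the F test. Against vehicle it gave 1349 to 2497 for abemaciclib 120, 46 to 531 for abemaciclib 36, 120 to 1317 for ribociclib, 0 to 1 for palbociclib 100 and 0 to 0 for palbociclib 30 (limma in each). Between groups it gave 397 to 1344 for the abemaciclib doses, 0 to 0 for the palbociclib doses, 2118 to 4781 for abemaciclib 120 against ribociclib, 1344 to 2643 against palbociclib 100, 17 to 641 for ribociclib against palbociclib 100 and 32 to 775 for abemaciclib 36 against palbociclib 30. The list counts ranged over 15 to 18 for abemaciclib 120, 2 to 16 for abemaciclib 36, 3 to 5 for palbociclib 100, 2 to 12 for palbociclib 30, 9 to 13 for ribociclib, 18 to 27 for abemaciclib 120 against ribociclib and 17 to 22 against palbociclib 100. The G2/M list turned to -0.072 for abemaciclib 36 without its replicate C (highest 0.466, without replicate B), the cholesterol list turned direction in the test for ribociclib without its replicate A (median 0.04, highest 0.501 without replicate B), and the fibroblast median became -0.18 without that array. Of the list calls over all 11 comparisons, 17 were lost with the RNA quality covariate, 15 with dim genes left out, 11 with quantile re-normalization, 10 with only the compared groups fitted, 7 with the block and 5 with the mean of all probe sets. The cause was not tested for any of these changes unless stated. At 3 arrays per group, dim signals and small folds limit what can be called.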

Other observations

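The splits of the arrays were planned, and the genes singled out in the paragraph on single arrays and those named for both abemaciclib doses were chosen after their values were seen.

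In total 213 genes were called at both abemaciclib doses, 39 higher and 174 lower, and 0 in opposite directions. Frat2 was lower at 36 and 120 mg/kg/day (-3.28 and -2.14), with -0.21 for palbociclib at 100 and 0.12 for ribociclib at 300 mg/kg/day. Haus6, of the augmin complex, was higher at both doses (2.63 and 2.36), with -0.36 and -0.20 for these compounds. Ppargc1a, the coactivator of mitochondrial biogenesis, was lower at both doses (-1.94 and -1.96) and with ribociclib (-2.47), with 0.22 for palbociclib. Cdkn2d, an inhibitor of CDK4 and CDK6, was lower at both doses (-1.94 and -1.70) and with ribociclib (-1.50), with -0.89 for palbociclib. The fold differences of the doses correlated across genes with r = 0.638, where genes are not independent replicates. Simulated unchanged groups that shared a simulated vehicle group, its values also drawn anew, gave a median of 0.532 (-0.078 to 0.847). The covariance was 0.197 against 0.036 simulated (-0.005 to 0.125), and independent lists would share 6.82 higher and 18.91 lower genes. Abemaciclib at 120 mg/kg/day and ribociclib shared 27 higher and 193 lower genes (13.63 and 32.7 for independent lists, 2 opposite), and abemaciclib at 36 mg/kg/day and ribociclib 19 higher and 103 lower (0.71 and 6.16). For these pairs the correlations of 0.251 and 0.48 lay below the simulated medians of 0.543 and 0.521, and the covariances of 0.083 and 0.099 lay within the simulated ranges of -0.003 to 0.141 and -0.008 to 0.121. The 3 vehicle arrays cannot be split with at least 2 on each side, and how much of each excess over independent lists comes from these shared arrays was not measured. Abemaciclib and ribociclib also shared a vehicle that differs from that of the vehicle arrays and of palbociclib. Its part in the genes shared by these compounds, and by the abemaciclib doses, cannot be told apart from that of the compounds. The simulated unchanged groups shared 0 called genes in limma at the median and at the upper end of the central 95% of 100 draws, the range also given for the other simulated values. With no group changed, limma is expected to call few genes, so this count cannot measure what the shared vehicle arrays add.

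Antimicrobial genes and goblet and early secretory genes moved in both directions with abemaciclib at 120 mg/kg/day. Of 11 measured antimicrobial genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.07, adjusted p = 0.782). The secreted protease inhibitor Slpi was 12.4-fold lower and the lectin Reg3b 6.25-fold lower, while the hydrogen peroxide-producing oxidase Duox2 was 6.60-fold higher. Of 19 goblet and early secretory genes, 4 rose and 2 fell (median 0.10, adjusted p = 0.4), with the secretory transcription factor Spdef at 2.36-fold higher. The incretin hormone Gip was 3.14-fold lower, the only 1 of 21 enteroendocrine genes to pass (median -0.11, adjusted p = 0.747). Among fatty acid oxidation genes 8 of 24 fell and 2 rose (median -0.27, adjusted p = 0.0856), with the peroxisomal enzyme Ehhadh at -1.45 and the thioesterase Acot1 at 2.12.

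Other splits of the arrays were fitted in the same way. The F test called 3212 genes for the real groups and at most 1461 in the other of 100 regroupings. Thus 1 of 100, the real one, was as large, which argues against a grouping by chance for this count. Each comparison of 3 with 3 arrays has only 10 splits, too few for a share under 0.05. For each, the number of splits with a count at least as large, the real one included, is given beside the real count and the highest other. For genes against vehicle these were 1 (2560 and 0) for abemaciclib 120, 1 (296 and 0) for abemaciclib 36, 1 (531 and 0) for ribociclib, 10 (0 and 1) for palbociclib 100 and 10 (0 and 2) for palbociclib 30. Between groups they were 1 (1079 and 36) for the abemaciclib doses, 10 (0 and 0) for the palbociclib doses, 1 (3865 and 9) for abemaciclib 120 against ribociclib, 1 (2598 and 0) against palbociclib 100, 1 (117 and 2) for ribociclib against palbociclib 100 and 1 (176 and 0) for abemaciclib 36 against palbociclib 30. For gene lists they were 4 (17 and 19) for abemaciclib 120, 10 (6 and 18) for abemaciclib 36, 10 (3 and 12) for palbociclib 100, 7 (6 and 14) for palbociclib 30, 8 (12 and 19) for ribociclib, 1 (22 and 19) for abemaciclib 120 against ribociclib and 3 (18 and 20) against palbociclib 100. Splits that mix the groups thus called up to 20 lists. For abemaciclib 36 and palbociclib 100 such splits called up to several times the real number. The real list counts are those at the preset correlation between genes, and with an estimated one they were 0 for both. A structure of the samples and correlation between genes could each give such calls, and these splits cannot tell them apart. Mixed splits also keep part of the treatment difference, and its share in these calls was not tested. The counts of 0 in the palbociclib comparisons are limma's, with 1023, 357 and 619 genes at an unadjusted p under 0.05 for 100 and 30 mg/kg/day against vehicle and between the doses. The counts of 357 and 619 are fewer than expected by chance.

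Several genes differed widely between arrays of a group. The MHC class II gene RT1-Bb was at 6.44 on vehicle replicate B and at 11.86 and 12.05 on the other vehicle arrays. The transcription factor gene Onecut2 was at 8.37 on vehicle replicate A, 6.99 on palbociclib 30 replicate A, 7.02 and 10.17 on palbociclib 100 replicates A and B and 9.65 on abemaciclib 36 replicate A, and between 3.76 and 4.66 on the other 13 arrays. Other genes of the region lists also stood apart on palbociclib 100 replicate B and abemaciclib 36 replicate A. The proximal genes Pdx1 (6.73 and 6.21, at most 4.61 elsewhere) and Slc40a1 (12.03 and 11.86, at most 10.99 elsewhere) were high there, and the ileum genes Nts (9.22 and 8.68, at least 10.07 elsewhere) and Pyy (4.95 and 4.76, at least 6.50 elsewhere) low. Both arrays are part of every comparison with their groups. Without abemaciclib 36 replicate A, 46 rather than 296 genes differed from vehicle and 32 rather than 176 from palbociclib 30, and without palbociclib 100 replicate B, 17 rather than 117 differed between ribociclib and palbociclib 100. Leaving out vehicle replicate C, palbociclib 30 replicate C or palbociclib 100 replicate C lowered these counts to a similar degree, as given above. The falls are thus not particular to the arrays that stood apart. Cyp1a1, induced through the aryl hydrocarbon receptor, was at 5.20, 12.92 and 9.33 on the vehicle arrays. Ly6al was at 10.94 on palbociclib 100 replicate C and at 5.81 and 5.03 on the others of that group. Gzma was at 7.28 on ribociclib replicate A and at 10.23 and 10.74 on replicates B and C.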
